A study of Rattus norvegicus with 5 samples.

How the data were processed

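Fat from the mesentery around the pancreas of 2 rats on a cafeteria diet and 3 rats on standard chow was measured on Affymetrix GeneChip rat genome arrays, 1 sample per array, with the samples described as independent per the labels. The values are log2 expression levels as the authors deposited them, with 1 value per probe set and array. The submitters' processing notes name RMA and the affy package, without versions, as the processing; RMA corrects the background, makes the array distributions alike and summarises the probes of a set. Making the distributions alike can hide a shift that moves most transcripts together. Further steps and array batches are not given in the sources used here.

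Samples were grouped by the diet in their titles and labels. The replicate numbers of the titles were not taken as pairs. Values identical between arrays were counted to look for a repeated array: 11.7% to 14.7% of probe sets matched exactly between any pair, and no pair was merged.

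From these values, the 57 control probe sets were left out and the probe sets kept were those whose mean over all 5 arrays lay above the 30th percentile, 21729 in all. Diets were compared with lmFit and eBayes of limma 3.58.1 in R 4.3.3, cafeteria minus standard, two-sided, with default settings. P-values were adjusted by Benjamini-Hochberg and called at 0.05. The fit had 3 residual degrees of freedom and a prior worth 1.50. For single genes an exact permutation test over the 10 splits of the 5 samples was run, whose smallest p is 0.1. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15. P-values of the probe set test measure the spread between these samples.

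Gene symbols came from GEO's platform annotation for the probe sets. It gave 1 symbol for 20826 probe sets, several for 436 and none for 9780, which are unnamed here. Of the probe sets with a symbol, 20758 had a gene identifier found in the RefSeq gene table, and 0 symbols changed. A gene with several probe sets was represented by the one with the highest mean over all arrays, and genes on probe sets with several symbols were not named. No genome coordinates are given, because no build is stated for the array.

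The genes named were set by rule before the data were examined. They are Igfbp3 and the members of the insulin-like growth factor list past the threshold, or its 3 with the smallest p; the 10 largest rises and 10 largest falls past the threshold, filled by the smallest unadjusted p where fewer pass; up to 4 members of each described list with the smallest p; and Lep and Adipoq for reference. For the fills, 1 probe set per gene was taken, that with the smallest p.

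A set of 45 gene lists was written at the same stage, on fat cell biology, metabolism, inflammation, growth factors and the cell types that tissue around the pancreas could hold. Lists with at least 5 measured genes, 44 in all, were tested over 11509 genes with limma camera at a preset inter-gene correlation of 0.01. With this preset the p-value compares a list's genes with the other genes. It does not measure how the list as a whole varies between samples. They were tested again with an estimated correlation and with fry, which tests whether a list's genes move one way on balance. The list of neutrophil markers had too few measured genes.

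The procedure was tested on simulated arrays that kept the real means and the moderated variances of the fit, with independent noise. Moderated variances differ less between probe sets than raw ones, so the shares called here can overstate the power on the real arrays. Of probe sets changed by 1 log2 unit, 75 of 96 were called at an adjusted p of 0.05, and of those changed by 2 units, 90 of 94. Among unchanged probe sets, 8 were called, and a list shifted by -0.4 was recovered at -0.38 with 1 unshifted list called in error. The simulation has no correlation between genes, so it does not cover the error of camera's preset correlation in real tissue.

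Alternatives were other filters, quantile and cyclic loess normalization of the deposited values, other variance models, array weights, probe sets without possible cross-hybridization, other gene summaries, a replicate block, and leaving out each array in turn. A covariate for acinar transcripts and camera on ranks were added after the data were seen.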

Results

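The data were 5 expression arrays of the mesenteric fat that lies around the pancreas of male Wistar rats. The animals were 7 weeks old at the start, and each array carried an independent sample. A set of 3 samples came from rats on standard chow, with 8% of calories as fat, and 2 samples came from rats on a cafeteria diet, with 66% of calories as fat, a regimen used to make rats obese. Each diet was given for 30 days. The values are log2 expression levels for 31099 probe sets, of which 57 are array controls and 21729 passed the filter on dim probe sets. The arrays had medians between 5.70 and 5.75 and correlated pairwise at 0.976 to 0.989 across probe sets. The number of arrays, 2 against 3, limits the precision of every comparison.

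The array of standard replicate 1 held transcripts of pancreatic acinar cells, the enzyme-secreting cells of the neighbouring organ. Of 19 acinar genes measured, 13 lay more than 2 log2 units above the highest other array there. These 19 are the ones that passed the filter among 33 on the array, and some passed only through their level in standard replicate 1. Pancreatic lipase (Pnlip) read 10.11 on that array and at most 4.45 on the others, and the amylase gene Amy2a3 read 9.68 against at most 3.12. The mean of the acinar list was 8.14 on this array and 4.55 to 4.82 on the other 4. Standard replicate 3 had the highest score for smooth muscle and pericyte genes, 1.14 log2 units above the mean of all arrays, and cafeteria replicate 1 had the highest cell cycle score, 0.41.

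**Figure D1:**
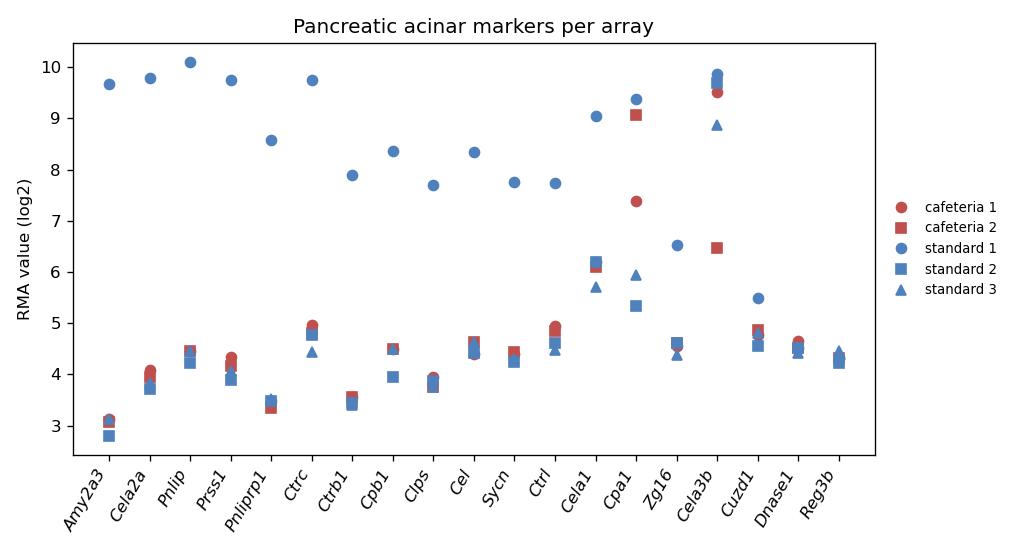
Log2 expression value (vertical axis) of each pancreatic acinar marker gene (horizontal axis) on the 5 arrays, 1 point per array, with colour for diet and shape for replicate. Standard replicate 1 lies over 2 log2 units above every other array for 13 of the 19 genes.

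The series is about insulin-like growth factor binding protein 3 (Igfbp3), a secreted carrier of insulin-like growth factors, so the first question was whether its expression in this fat depot differed between diets. Igfbp3 had a lower mean in cafeteria samples, 9.39 ± 0.73 (SD, n = 2), than in standard samples, 10.77 ± 0.37 (SD, n = 3). The difference was -1.38 ± 0.39 (SE) on the log2 scale, with a 95% interval of -2.42 to -0.34, which corresponds to a 2.61-fold lower level. Its second probe set gave -1.37 ± 0.27. Both cafeteria arrays lay below all standard arrays for either probe set. The difference did not pass the test over all probe sets (limma, adjusted p = 0.317 for the brighter probe set and 0.262 for the other), and the exact permutation test, two-sided, gave p = 0.1, the smallest that 10 splits of 5 samples allow. The size rested on which cafeteria array was used: it was -1.90 without cafeteria replicate 1 and -0.87 without cafeteria replicate 2.

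The other members of the insulin-like growth factor system were mostly lower too, 15 of 18 including Igfbp3, with a list mean of -0.30, but the list missed the threshold of the gene list test (limma camera, adjusted p = 0.0585). It passed without cafeteria replicate 1, at a mean of -0.45 (adjusted p = 0.00562), and without standard replicate 1, at -0.37 (adjusted p = 0.0295), and also with cyclic loess, camera on ranks or an acinar covariate, and its adjusted p was 0.542 with an estimated correlation. Without cafeteria replicate 2 the mean was only -0.15 (adjusted p = 0.603), and without standard replicate 3 it was -0.24 (adjusted p = 0.290). Pappa2, a protease that cuts IGF binding proteins, differed by -1.35 ± 0.54 on its brighter probe set and by 0.11 ± 0.18 on its other one, and the brighter one gave -0.89 without standard replicate 2. Igfbp7, a related binding protein, differed by -0.22 ± 0.09, by -0.34 without cafeteria replicate 1 and by -0.10 without cafeteria replicate 2. No member passed the test over all probe sets, and 0 passed when adjusted over the list alone.

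Leptin (Lep), the hormone that fat cells release in proportion to fat stores, read 10.66 in cafeteria and 9.07 in standard samples, a difference of 1.59 ± 0.20 or 3.01-fold, and adiponectin (Adipoq) differed by 0.16 ± 0.09, by 0.24 without cafeteria replicate 1 and by 0.07 without cafeteria replicate 2. Neither passed the test over all probe sets (limma, adjusted p = 0.222 and 0.497). Over the adipokine list alone, Lep had an adjusted p of 0.0241.

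**Figure D2:**
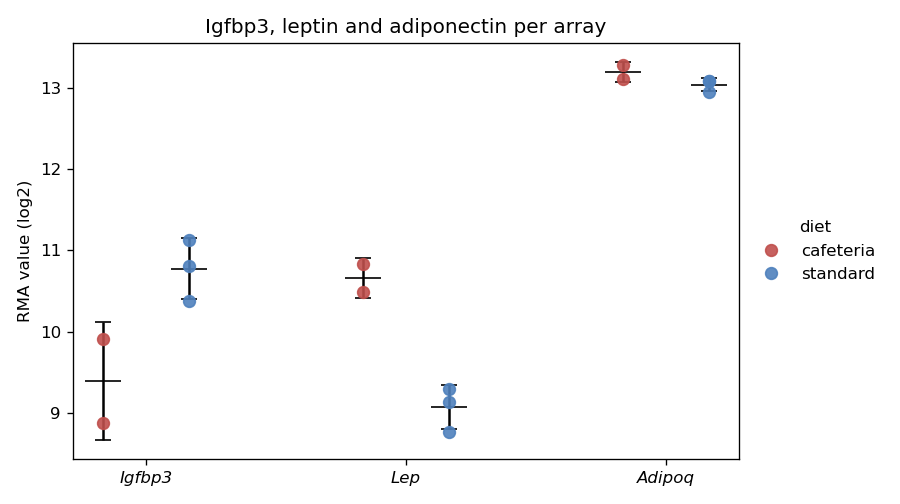
Log2 expression value (vertical axis) of Igfbp3, Lep and Adipoq on each array, coloured by diet, with the group mean as a horizontal mark and the SD as bars (n = 2 cafeteria, n = 3 standard). Both cafeteria arrays lie below the standard arrays for Igfbp3 and above them for Lep, and the Adipoq means differ by 0.16.

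The second question was which other transcripts differed between the diets. No probe set passed an adjusted p of 0.05 in limma, the smallest being 0.0958, and 0 passed in a per-probe-set test without moderated variance. At an unadjusted p under 0.05 there were 2754 probe sets, 1315 higher and 1439 lower in cafeteria samples, where 1086 would be expected by chance, and 4171 when cafeteria replicate 1 was left out. Without standard replicate 1, the array with acinar transcripts, there were 2069. The 2 groups of arrays did not overlap for 27.4% of probe sets, against 20% by chance.

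The genes named next are those with the smallest unadjusted p in each direction, and none is past the threshold. Higher in cafeteria samples were Dlg2, a synaptic scaffold protein, by 2.25 ± 0.14, the lens-type galectin gene Grifin by 1.83 ± 0.17, and Cryab, a small heat shock protein, by 1.44 ± 0.08. Adra2c, an alpha-2 adrenergic receptor, differed by 1.32 ± 0.10, Hoga1 by 1.26 ± 0.12, C10h17orf58 by 1.10 ± 0.05, and the inositol transporter Slc2a13 by 0.97 ± 0.06. Ccser2, Asah2 and Ythdf2 lay 0.90, 0.87 and 0.84 higher, although a second Ythdf2 probe set gave 0.21, another Hoga1 probe set 0.24 and a second Asah2 probe set 0.47. Adjusted p ranged from 0.0958 to 0.171 over these genes.

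Lower in cafeteria samples were RT1-Bb and RT1-A, genes of the rat major histocompatibility complex, by -4.13 ± 0.25 and -1.70 ± 0.11. A second RT1-Bb probe set gave 0.05 ± 0.12, so the probe sets of this gene disagreed. Snap25, a protein of vesicle release, differed by -1.45 ± 0.08, Ch25h, the enzyme that makes 25-hydroxycholesterol, by -1.28 ± 0.10, Akr1c15 by -1.09 ± 0.07, and the organic cation transporter Slc22a3 by -1.03 ± 0.06. Both cafeteria arrays held the identical Ch25h value, 5.96, so its SE may be too small. Ifgga2l1 lay at -0.93, Ncoa7 at -0.87, Dusp6, a phosphatase that restrains ERK signalling, at -0.78, and the endothelial receptor Adgrl4 at -0.70. The other Dusp6 probe sets gave -0.62 and -0.31, and the arrays of the 2 diets overlapped on the last. The smallest adjusted p among them was 0.0958 and the largest 0.171.

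The third question was whether gene groups fixed beforehand shifted with diet. Of 44 lists tested, limma camera with a preset correlation called 23, with 13 higher and 10 lower in cafeteria samples. None was called with a correlation estimated from the arrays, where the smallest adjusted p was 0.542, and none by fry, whose smallest adjusted p was 0.0842. When the 5 arrays were divided in the 9 other possible ways into 2 and 3, camera called between 6 and 25 lists, so a count of 23 is within the range of the other groupings. The 25 came from standard replicates 1 and 2 against the rest, which keeps both cafeteria arrays together and still reflects diet in part. Splits that paired 1 cafeteria array with 1 standard array called 6 to 22 lists, so 23 is only just above them. No member of any list passed the test over all probe sets. The means of the called lists are given next as measured shifts.

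Several lists of fat cell function were higher in cafeteria samples. Adipocyte identity genes had a mean difference of 0.27, with 20 of 23 members higher (adjusted p = 8.20e-06, and adjusted p = 0.542 with an estimated correlation). Of these, 2 were higher and 1 lower when adjusted over the list alone: Acsl1, which activates fatty acids, by 0.46, the lipid droplet protein Plin4 by 0.84, and complement factor D (Cfd), made by fat cells, by -0.40. Lipolysis and lipid droplet genes had a mean of 0.26, with 21 of 25 higher (adjusted p = 1.35e-05, and adjusted p = 0.542 with an estimated correlation). Adjusted over the list alone, 1 member was higher, Plin4, and 1 lower, Adra2a, an adrenergic receptor that restrains lipolysis, by -1.57. PPARG target genes averaged 0.23, with 16 of 20 higher (adjusted p = 0.000231, and adjusted p = 0.542 with an estimated correlation), and 2 were higher adjusted over the list alone. These lists share members: 18 of the 23 adipocyte genes and 16 of the 20 PPARG targets stand on another list. Without cafeteria replicate 2 the means were 0.16 for adipocyte identity, 0.17 for lipolysis and 0.15 for PPARG targets, and the last was 0.14 without standard replicate 1 and 0.15 with an acinar covariate. Standard replicate 1, the array with acinar transcripts, scored lowest of the arrays on these lists, at -0.26, -0.24 and -0.27. Without that array the medians of adipocyte identity and lipolysis were 0.22 and 0.21, against 0.30 for both over all arrays. Both lists stayed called.

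Genes of fatty acid oxidation were higher by 0.27 on average, 26 of 29 (adjusted p = 8.20e-06, and adjusted p = 0.542 with an estimated correlation), with 2 higher adjusted over the list alone: the fatty acid binding protein Fabp3 by 1.70 ± 0.19 and the ketone enzyme Bdh1 by 0.69 ± 0.09. Bdh1 read below the array medians, at 5.24 in cafeteria samples against 4.55. Oxidative phosphorylation genes lay 0.13 higher, 50 of 51 (adjusted p = 5.24e-07, and adjusted p = 0.542 with an estimated correlation), with 0 adjusted over the list alone. Ndufb6 was at 0.29 and Cox8a at 0.27, while the mean was 0.06 without cafeteria replicate 2 (adjusted p = 0.0801) and 0.20 without cafeteria replicate 1. Cholesterol synthesis averaged 0.23 (adjusted p = 0.00175, and adjusted p = 0.542 with an estimated correlation), with Insig1 at 0.82, and was no longer called at 0.15 without cafeteria replicate 2. Standard replicate 1 scored lowest of the arrays on the lists of fatty acid oxidation, oxidative phosphorylation and cholesterol synthesis. Without that array their medians were 0.16, 0.09 and 0.15, against 0.27, 0.13 and 0.23 over all arrays, and all stayed called. Brown fat and thermogenesis genes averaged 0.23 (adjusted p = 0.0239, and adjusted p = 0.542 with an estimated correlation), with 1 higher adjusted over the list alone, Fgf21 at 0.55. Fgf21 read below the array medians, at 5.35 in cafeteria samples against 4.80. The brown fat list mean was 0.08 without cafeteria replicate 2 and 0.37 without cafeteria replicate 1. Its call was lost without standard replicate 1, at 0.14. Omitting the filter on dim probe sets also ended it, at 0.12 (adjusted p = 0.189). Adipokines averaged 0.11 (adjusted p = 0.0246, and adjusted p = 0.542 with an estimated correlation), with 3 higher and 1 lower adjusted over the list alone, and 0.03 without cafeteria replicate 1, which ended the call. Without cafeteria replicate 2 the adipokine mean was 0.18.

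Extracellular matrix genes were higher by 0.18 on average, 38 of 47 (adjusted p = 0.000136, and adjusted p = 0.542 with an estimated correlation), with 0 adjusted over the list alone. Periostin (Postn) lay 1.14 ± 0.27, Fbln2 0.90 ± 0.21 and Sparc 0.43 ± 0.08 higher. Fibroblast and preadipocyte markers averaged 0.22 (adjusted p = 0.0423, and adjusted p = 0.542 with an estimated correlation), with Mfap5 at 0.81 and Pi16 at 0.78. Leaving out cafeteria replicate 1, cafeteria replicate 2 or standard replicate 3 ended that call, with means of 0.21, 0.24 and 0.16, and so did omitting the filter and cyclic loess (adjusted p = 0.123 and 0.0858). Nerve and Schwann cell markers averaged 0.17 (adjusted p = 0.000913, and adjusted p = 0.542 with an estimated correlation), and 0.11 with no filter. Adjusted over the list alone, 2 were higher, S100b at 0.51 and the myelin gene Mbp at 0.34. S100b read 12.98 in cafeteria samples against 12.47 in standard samples. Sox10, another member, differed by 0.27 and read only 4.47 in cafeteria samples. Which cells gave the S100b signal was not tested. Intestinal epithelium markers, with 5 of 16 genes on the array past the filter, averaged 0.22 (adjusted p = 0.00206, and adjusted p = 0.542 with an estimated correlation), with 4 higher adjusted over the list alone. These included Slc5a1 and Apoa4 at low levels, 4.63 and 4.41 in cafeteria samples against 4.40 and 4.23, and with no filter the list mean was 0.12, still called (adjusted p = 0.00508). Cell cycle genes averaged 0.20 (adjusted p = 0.0111, and adjusted p = 0.738 with an estimated correlation). Without cafeteria replicate 1 their mean was -0.09, without cafeteria replicate 2 it was 0.49, and the call also ended without standard replicate 2 or 3, at 0.18 and 0.17, and with a filter at the 50th percentile (adjusted p = 0.121).

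Several immune lists were lower in cafeteria samples. Interferon response genes differed by -0.44 on average, with 30 of 32 lower (adjusted p = 3.98e-08, and adjusted p = 0.542 with an estimated correlation). Adjusted over the list alone, 2 were lower: the immunoproteasome subunit Psmb8 by -1.28 ± 0.15 and the transcription factor Irf1 by -0.62 ± 0.08. The class II antigen presentation list averaged -0.49, with 10 of 12 lower (adjusted p = 0.000136, and adjusted p = 0.542 with an estimated correlation) and 4 lower adjusted over the list alone. These were the class II master regulator Ciita by -0.75, the invariant chain Cd74 by -0.52, RT1-Db1 by -0.74 and RT1-Ba by -1.40. Of the 12 genes 6 belong to the RT1 region, where probe sets of a gene can disagree, as 3 further RT1-Ba probe sets did at 0.12, -0.0095 and -0.21. The other 6 genes averaged -0.36.

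Genes of the NF-kB pathway averaged -0.22, with 16 of 19 lower (adjusted p = 0.000913, and adjusted p = 0.542 with an estimated correlation), and 3 were lower adjusted over the list alone: Tnfaip3 by -0.87, Birc3 by -0.49 and Nfkb1 by -0.32. Cytokines and chemokines averaged -0.39 (adjusted p = 0.00813, and adjusted p = 0.542 with an estimated correlation), and -0.27 without cafeteria replicate 2, when the list was no longer called. Adjusted over the list alone, the eosinophil attractant Ccl11 was lower by -1.99 ± 0.36 and Ccl19 by -0.62 ± 0.09, while Tnf was higher by 0.25 ± 0.05. Tnf read below the array medians, at 5.04 in cafeteria samples against 4.79. Complement genes averaged -0.25 (adjusted p = 0.0361, and adjusted p = 0.542 with an estimated correlation), with Clu at -0.74 and 2 lower adjusted over the list alone. The complement call ended without cafeteria replicate 2, standard replicate 1 or standard replicate 2, at -0.13, -0.20 and -0.23, and also with no filter (adjusted p = 0.0714) or with an acinar covariate (adjusted p = 0.116).

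Among cell type markers, endothelial genes averaged -0.40, with all 22 lower (adjusted p = 6.89e-06, and adjusted p = 0.542 with an estimated correlation), and Sox17 at -0.76 and Egfl7 at -0.65 were the 2 lower adjusted over the list alone. The endothelial mean was -0.12 without cafeteria replicate 1, with no call, and -0.69 without cafeteria replicate 2. T cell markers averaged -0.45, with all 19 lower (adjusted p = 0.000117, and adjusted p = 0.542 with an estimated correlation), but -0.20 and no call without cafeteria replicate 2, and -0.69 without cafeteria replicate 1. Mast cell markers averaged -0.56 (adjusted p = 0.000739, and adjusted p = 0.564 with an estimated correlation), with 1 lower adjusted over the list alone, Gata2 at -0.60. Without cafeteria replicate 2 the mast cell mean was -0.17, with no call, and without cafeteria replicate 1 it was -0.95. Macrophage markers averaged -0.24 (adjusted p = 0.00384, and adjusted p = 0.642 with an estimated correlation), with the galectin Lgals3 at -0.42 and Trem2 at 0.40. They were not called without cafeteria replicate 2, at -0.12, or without standard replicate 1, at -0.15, and lay at -0.36 without cafeteria replicate 1 and -0.38 without standard replicate 3. Genes of the cytosolic ribosome averaged -0.15, with all 31 lower (adjusted p = 1.98e-06, and adjusted p = 0.542 with an estimated correlation), -0.06 without cafeteria replicate 2 and -0.25 without cafeteria replicate 1.

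**Figure D3:**
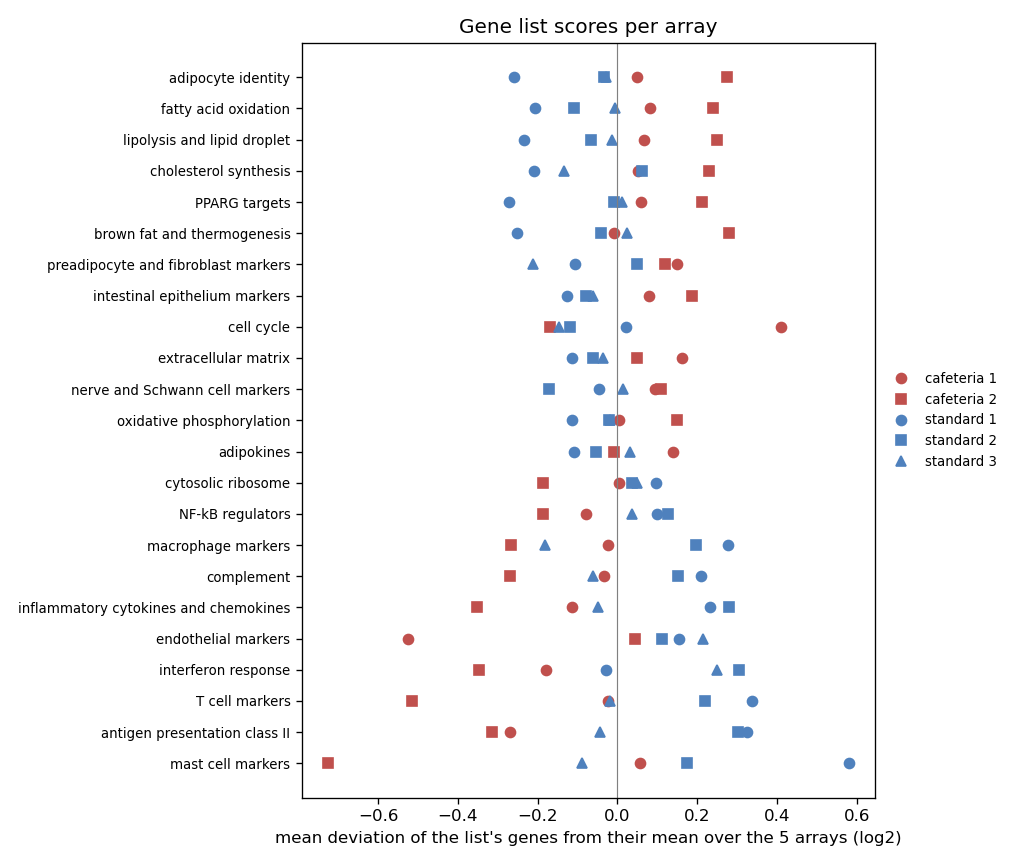
Mean log2 deviation of each called list's genes from their mean over the 5 arrays (horizontal axis), with 1 point per array, coloured by diet and shaped by replicate, and lists on the vertical axis. For 16 of the 23 called lists both cafeteria arrays lie on the same side of all standard arrays, and the cell cycle score stands highest on cafeteria replicate 1, at 0.41.

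The remaining 21 lists were not called. The marker lists among them were lymph node stroma at a mean of -0.34 (adjusted p = 0.0534), B cells and plasma cells at -0.39, smooth muscle and pericytes at -0.56, red blood cells at 0.21, mesothelium at 0.03, skeletal muscle at -0.10 and pancreatic islets and ducts at -0.15. Acinar markers averaged -0.99 (adjusted p = 0.151, and adjusted p = 0.786 with an estimated correlation), and 0.20 with a call (adjusted p = 0.00383) once standard replicate 1 was left out, and -1.60 with a call without standard replicate 2. The filter still used standard replicate 1, so the 0.20 includes genes near the floor elsewhere, such as Amy2a3 and Ctrb1, at most 3.12 and 3.57. Elsewhere Cpa1 read 7.38 and 9.07 in cafeteria against 5.34 and 5.94 in standard samples. Cela3b went the other way, at 9.52 and 6.46 against 9.70 and 8.88. Several results of the lists not called rested on single arrays. Without cafeteria replicate 1 there were calls for B cells at -0.70, lymph node stroma at -0.62, red blood cells at 0.39, mesothelium at -0.30, glucocorticoid response genes at -0.35, immediate early genes at 0.42 and the TCA cycle at 0.16. Over all 5 arrays these lists had adjusted p = 0.542 to 0.915 with an estimated correlation. Without cafeteria replicate 2 the means were -0.09 for B cells, -0.07 for lymph node stroma, 0.03 for red blood cells, -0.10 for glucocorticoid response genes, -0.09 for immediate early genes and -0.00086 for the TCA cycle, with no call, while mesothelium was called at 0.36 (adjusted p = 0.915 with an estimated correlation over all arrays). Smooth muscle was called at -1.01 without standard replicate 2 and lay at -0.10 without standard replicate 3, and the TCA cycle was called at 0.12 and 0.11 without these arrays (adjusted p = 0.742 and 0.738 with an estimated correlation over all arrays). Lymph node stroma was also called with cyclic loess (adjusted p = 0.0343) and with the mean of all probe sets of a gene (adjusted p = 0.0408), and had an adjusted p of 0.542 with an estimated correlation. The metabolic lists were the TCA cycle at 0.08, glycolysis at 0.07, de novo lipogenesis at -0.06, insulin signalling at -0.03, oxidative stress defence at 0.09 and the circadian clock at 0.11. Hypoxia response genes averaged 0.01, glucocorticoid response genes -0.22, immediate early genes 0.16, matrix remodelling enzymes 0.02 and the unfolded protein response 0.0046. Secreted growth factors averaged 0.01, with 17 members higher and 17 lower, of which 4 and 3 passed when adjusted over the list alone, among them Gdf10 at -1.39, Fgf18 at 1.07 and the inhibin subunit gene Inhbb at 1.03. Median and mean differed in sign for the islet and duct, skeletal muscle and unfolded protein response lists.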

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

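In this part the values with an array left out, the estimated correlation and the count of called lists over the other splits were planned before their results were seen; the tests of explanations, including those that use these values, the controls and the count of probe sets over the splits were chosen after.

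The 9 hybridisation control probe sets, which detect transcripts added in fixed amounts and enter no comparison, read higher on both cafeteria arrays than on every standard array, by 0.42 log2 units on average (exact permutation p = 0.5). Standard replicate 1 alone lay 1.07 below the mean of the other 4 arrays, and without it the difference was 0.08.

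RT1-Bb stood far below the rest on one probe set, at -4.13. A lower transcript level, or fewer cells carrying it, would move the gene's other probe set as well, and that one differed by 0.046, with an interval of -0.26 to 0.35. Both cafeteria arrays held the identical value on it, 9.44, so that interval may be too narrow. A sequence variant under the probes remains a candidate explanation, since Wistar rats are outbred and this region is highly variable. The 4 other RT1 genes with several probe sets had a mean within-gene range of 0.64. That lay at the 99.86th percentile of 10000 random sets of genes with as many probe sets. RT1-Ba is 1 of these 4, and its further probe sets did not follow its -1.40. The percentile may thus rest largely on RT1-Ba and does not show that RT1 genes in general disagree. Paralogous RT1 transcripts binding the same probes were not tested apart from a sequence variant. The same caution covers RT1-A at -1.70 and RT1-Ba at -1.40, and probe sequences were not used here.

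Several immune lists were lower in cafeteria samples. Acinar tissue in standard replicate 1 is argued against as the whole cause for most of them, because 8 of the 10 lower lists stayed called without that array. These 10 include the endothelial and cytosolic ribosome lists, which are not immune and stayed called. The macrophage and complement lists lost their call (limma camera, adjusted p = 0.0829 and 0.132). Over the 10 lists the means were -0.13 to -0.54 without that array, against -0.15 to -0.56 with it. None of the 10 was called with an estimated correlation (limma camera, adjusted p = 0.542 to 0.642). A larger share of fat cell RNA would lower every other cell type alike. Yet fibroblast markers lay 0.62 above the endothelial, T cell, mast cell and macrophage markers in their diet difference. The SE was 0.11 over 17 and 79 genes, and the difference was 0.53 to 0.69 with any array left out. That SE treats genes as independent and does not measure the spread between samples. Over the arrays the exact permutation test gave p = 0.1, the smallest that 10 splits allow. The difference goes against dilution acting alone, but dilution together with more fibroblasts was not tested. Less lymphoid tissue in cafeteria replicate 2 alone would not lower the class II list on cafeteria replicate 1. The list scored -0.27 there and -0.32 on replicate 2. Without cafeteria replicate 2 it lay at -0.46 (limma camera, adjusted p = 0.0150), a value that rests on 1 cafeteria array and the preset correlation. Uneven lymphoid tissue over all arrays stays open. Class II scores ran from 0.32 to -0.04 over the standard arrays, and T cell scores from 0.34 to -0.02. Less lymphoid tissue in cafeteria replicate 2 also stays open for T cell and mast cell markers, whose calls ended without it. The same holds for lymph node stroma and B cell markers, at -0.069 and -0.092 without that array. An effect of diet stays open, since 10 splits are too few for a share under 0.05: the real split called 23 lists, the highest other, standard replicates 1 and 2 against the rest, called 25, and 2 of the 10 splits gave 23 or more.

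Igfbp3 was lower by a mean of -1.38. A faulty probe set is argued against, as the 2 probe sets differed by 0.011 in their diet difference, and so is the acinar tissue of standard replicate 1, without which the difference was -1.58. Fewer endothelial cells, which make Igfbp3 among other cells, cannot be told apart from a change within cells: the endothelial mean of -0.40 lies inside the interval of the brighter Igfbp3 probe set, -2.42 to -0.34, but above that of the other, -2.10 to -0.64. The 2 cafeteria arrays also differ here, with an endothelial mean of -0.12 and Igfbp3 at -1.90 without cafeteria replicate 1, and -0.69 and -0.87 without cafeteria replicate 2. The effect of diet itself stays open, as no setting brought Igfbp3 past the threshold.

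At an unadjusted p under 0.05, the real split gave 2754 probe sets and the highest other split 1249, and 1 of 10 splits reached the real count. That share cannot go under 0.05 with 10 splits.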

How the results depend on the processing

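The acinar covariate, camera on ranks, and the counts at an unadjusted p under alternatives were added after the data were seen. No probe set was called under any alternative run. Igfbp3 stayed negative and uncalled throughout, with -0.87 to -1.90 over arrays left out. The 168 values of other named genes under alternatives kept their direction, with 0 past the threshold. The count of called lists was 0 with an estimated correlation and 0 by fry, both tests that allow for correlation between genes, and 15 to 27 over arrays left out, with 15 without cafeteria replicate 2. Of single list values under alternatives, 73 lost their call, 23 gained one and 20 changed sign. The count at an unadjusted p under 0.05 was 1981 to 4171 over arrays left out. The replicate numbers were not taken as pairs, and deviations from the group means correlated at 0.08 and -0.04 between same-numbered arrays. The deviations of the 2 cafeteria arrays mirror each other, so these values are not separate checks and cannot exclude a shared batch. Standard replicate 3 has no same-numbered partner, so the replicate block also takes that array out of the diet estimate. With the replicate block, Igfbp3 was at -1.20 (limma, adjusted p = 0.527), 25 lists and 0 probe sets were called, the fibroblast list lost its call (adjusted p = 0.0659), lymph node stroma, TCA cycle and acinar lists gained one at -0.39, 0.11 and -1.58 (adjusted p = 0.0154, 0.0286 and 0.0111), and the means of matrix remodelling, mesothelial and unfolded protein response lists turned to -0.033, -0.024 and -0.044. Secreted growth factors turned to -0.018 with the stricter filter and the hypoxia list to -0.014 with the acinar covariate. Over arrays left out, list means that changed sign ranged from -0.089 to 0.49 for cell cycle, -0.30 to 0.36 for mesothelium, -1.60 to 0.20 for acinar cells, -0.053 to 0.079 for secreted growth factors, -0.24 to 0.10 for de novo lipogenesis, -0.032 to 0.048 for hypoxia, -0.00086 to 0.16 for the TCA cycle, -0.37 to 0.059 for islets and ducts, -0.044 to 0.032 for the unfolded protein response, -0.094 to 0.42 for immediate early genes and -0.033 to 0.060 for matrix remodelling. The cause was not tested. With 1 cafeteria array left, that array is assumed to vary like the standard ones. Signal over background is not given by these values, so its limits on dim probe sets are unknown.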

Other observations

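The muscle test in this part and the genes named outside the fixed lists were chosen after the values were seen, while the mast cell list and leaving out each array were planned; none of the genes passed the adjusted threshold, and the genes were not tested as groups. Milr1, an inhibitory receptor of mast cells, lay lower in cafeteria samples by -2.07 ± 0.24, Ccl11 by -1.99 ± 0.36 and Enpp3, a surface enzyme of basophils and mast cells, by -1.02 ± 0.22, with both cafeteria arrays below all standard arrays for each. The mast cell list, fixed beforehand, was at -0.17 with no call without cafeteria replicate 2. Il1rl1, the receptor for interleukin 33, differed by -2.55 ± 0.74, but read 7.59 and 5.15 on the cafeteria arrays, and its second probe set gave -0.64.

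Higher in cafeteria samples were Myl4 by 1.95 ± 0.29, Sync by 1.69 ± 0.18, Klhl31 by 1.49 ± 0.42, and Ldb3 by 1.49 ± 0.17 on its highest probe set. These genes are known from striated muscle, but skeletal muscle in the dissected tissue is argued against as the source of rises this large: the 8 muscle markers measured had a median difference of 0.089 and a mean of -0.10 (SE 0.19 over genes), far below a rise of 1 log2 unit. Of these markers 5 were higher, with Myh1 at 0.37, Myl1 at 0.29 and Tnnt3 at 0.28, and 3 lower, with Acta1 at -1.27, Myoz1 at -0.39 and Eno3 at -0.27. These 8 are the ones that passed the filter on dim probe sets among 22 muscle markers on the array. A small share of muscle is not excluded, since 4 of the 8 averaged only 4.64 to 5.10 and Myh1 averaged 10.43. The Myh1 probe set is of a kind open to cross-hybridization, and the choice of markers for this test was widened after a first result.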
